A study of Mus musculus with 8 samples.

How the data were processed

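Ribosome footprints were profiled in naive CD4+ T cells of WT and Mettl3 KO mice, with 2 footprint libraries and 2 input RNA libraries per genotype, 8 samples in all. Per the labels' protocols, cells were treated with cycloheximide at 0.1 mg/ml for 1 min, footprints and input RNA were made into libraries with a commercial ribosome profiling kit, and libraries were amplified for 9 PCR cycles. Samples were grouped by genotype and library kind as their titles give them.

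Per the file headers, the table the authors deposited holds FPKM, fragments per kilobase of gene model scaled to the library's read total, with 1 column for each of the 4 footprint libraries and replicates not pooled. Per the submitters' processing notes, TopHat and Cuffdiff and the genome build mm10 (GRCm38) were used, with no versions and no order of steps. The gene annotation, the use of strand, the assignment of reads that match several genes, the removal of ribosomal RNA and any scaling between libraries are not given in the sources used here. Reads from overlapping genes on opposite strands therefore cannot be told apart with certainty. Estimates of this kind can list a gene at or near 0 although reads of it exist, and FPKM of a library depends on what share of its reads fell on abundant small RNAs. The input RNA values were not analysed here, and neither the planned test of translational efficiency nor that of input RNA was run. The authors' own test, planned as an alternative if the table held it, was not used here either.

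The table lists 23156 genes, of which 7563 are at 0 in all 4 libraries. No read totals accompany FPKM, so the depth was estimated from low genes. Among 5248 genes with a single annotated transcript, the most frequent value of FPKM times transcript length, within the range of the lowest peak, was taken as that of 1 read, which gave 5730000, 3400000, 5830000 and 2810000 reads for WT 1, WT 2, KO 1 and KO 2. The most frequent ratios of low values in WT 1 to those in WT 2, KO 1 and KO 2 were 0.612, 1.046 and 0.503, which give the relative depths without an annotation. Because the lengths the authors used are unknown, counts were not rebuilt from FPKM.

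Small RNA genes (1204 by symbol) were left out, since they are not translated. Genes were kept where the mean FPKM over the 4 libraries was at least 1, which left 9272, of which 8826 are protein-coding in GENCODE M21 (GRCm38). Coordinates, gene types and exon overlaps come from that annotation by gene symbol, which matched 22630 genes to 1 entry each. Values were transformed to log2(FPKM + 1), and a fold change is on this scale, which understates the change of low genes. Genotypes were compared with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-dependent trend, two-sided, 2 residual degrees of freedom plus 5.17 prior ones), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Intervals have a level of 95%. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

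Before the data were examined, 31 gene lists, the tests, the rule for named genes and the alternatives were fixed. The lists cover m6A factors, the SOCS family, IL-7 receptor, JAK and STAT5 signalling, apoptosis, naive, effector and regulatory T cell genes, T cell receptor signalling, immediate early genes, ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, oxidative phosphorylation (nuclear and mitochondrial), stress responses, interferon response, proliferation, histones, lipid synthesis, glycolysis, and markers of T, CD8 T, B, NK, myeloid, erythroid, platelet, thymocyte and stromal cells. The 25 lists with at least 5 tested genes were compared with all other genes by camera (limma) with its preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were the alternatives. The rule named Mettl3, the 12 highest and 12 lowest fold changes among called genes with a mean of at least 5 FPKM and KO libraries on 1 side of the WT libraries, up to 4 called members of each list by p, the 2 members of highest mean in lists with fewer than 2 called members, the SOCS family, and Il7r, Stat5a, Stat5b, Bcl2, Mettl14, Wtap and Ythdf2. Values of 3 genes the rule names are not reported here.

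Alternatives changed the pseudocount, the filter on low genes, the scaling, the treatment of small RNA genes, the variance trend, the replicate block and each library in turn. When a library was left out, its genotype had 1 library, which was assumed to vary like the other genotype. Settings added after the data were seen were protein-coding genes only, genes without exon overlap, genes without a genotype below 1 read, and limma's array weights.

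The fits were tested on simulated data. In 10 simulations of 9272 genes with the WT means and the spread limma estimated, 200 genes of at least 5 FPKM were changed, and 65.5% of the 2-fold and 98.5% of the 4-fold changes were called. Of the calls, 5.37% were false. Variances came from limma's own model with normal errors of equal size in all libraries, so a share near the threshold follows from the setting. It does not cover the lower depth of replicate 2 or values far below 1 read. camera called 0 of 200 unchanged lists and 10 of 10 shifted lists. Errors were drawn independently for each gene, and every member of a shifted list was moved by a 2-fold change. The simulations therefore did not test lists of correlated genes or lists with smaller shifts.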

Results

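Ribosome profiling sequences the short stretches of mRNA that ribosomes cover and protect from nuclease, so the footprint level of a gene reflects both how much of its mRNA a cell holds and how densely ribosomes occupy it. Footprints were measured in naive CD4+ T cells, helper T cells that have not yet met their antigen, from wild-type (WT) and Mettl3 knockout (KO) mice. Mettl3 is the catalytic subunit of the complex that writes the methyl mark m6A on mRNA. Each genotype had 2 footprint libraries, made from cells held for 1 min in cycloheximide at 0.1 mg/ml, which stalls ribosomes on the mRNA. The 4 input RNA libraries that accompany them were not analysed here, so a changed footprint level cannot be divided into a change of mRNA and a change of translational efficiency. The labels do not say that the duplicates came from separate animals, and p-values therefore measure the spread between these libraries, which may be technical.

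Footprint levels were given for 23156 genes as fragments per kilobase of gene, scaled to the library's read total (FPKM). The depth estimated from the size of a single read was 5730000 and 3400000 reads in WT libraries 1 and 2, and 5830000 and 2810000 reads in KO libraries 1 and 2. A gene with 1 read in KO library 2 therefore stood at a higher FPKM than a gene of the same length with 1 read in KO library 1, and low values were less precise in replicate 2 of each genotype. Small RNA genes held 43.7% and 37.0% of the summed FPKM of the WT libraries and 55.7% and 49.4% of that of the KO libraries, and they were left out of the tests. Across the 9272 genes tested, the Pearson correlation of log2(FPKM + 1), taken across genes, which are not independent replicates, was 0.972 between the WT libraries and 0.971 between the KO libraries. Between genotypes it ranged from 0.942 to 0.963.

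The targeted gene was examined first. Mettl3, on chromosome 14 at 52294841 to 52305128 (GENCODE M21, GRCm38), stood at 24.5 and 21.1 FPKM in the WT libraries and at 2.44 and 3.32 FPKM in the KO libraries. Its mean fell from 22.8 ± 2.41 (SD, n = 2) to 2.88 ± 0.624 FPKM (SD, n = 2), a log2 fold change of -2.62 (SE 0.18, limma adjusted p = 0.00216). An exon of Mettl3 overlaps an exon of Tox4 in the annotation, and part of the remaining signal cannot be assigned to either gene. A gene-level value may also include exons outside the deleted part of Mettl3, whose extent was not examined here. Over its alternative settings the adjusted p of Mettl3 ranged from 0.000544 to 0.166. The highest came with no filter on low genes, and without KO library 2 it was 0.0512. No other m6A factor passed the threshold. Mettl14, the partner of Mettl3 in the writer complex, had 8.52 ± 0.628 FPKM in WT and 8.73 ± 1.92 FPKM in KO. Wtap, a further subunit, had 31.1 FPKM and 41.8 FPKM, and Ythdf2, a reader that promotes mRNA decay, had 13.8 FPKM and 19.3 FPKM (log2 fold change 0.46, limma adjusted p = 0.157). Of the 17 tested writers, erasers and readers, Mettl3 was the 1 gene past the threshold, over all genes and adjusted over the list alone. The 2 most abundant others, Hnrnpc (66.4 FPKM in WT, 61.7 FPKM in KO) and Hnrnpa2b1 (55.7 FPKM in WT, 45.3 FPKM in KO), had log2 fold changes of -0.10 and -0.31. The list had a median of -0.03 and a camera adjusted p of 0.331, with the sign of its test (up) opposite to that of its median and mean. The test sets a list against all other genes, and the median of all tested genes was -0.10.

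Footprints differed between genotypes at 205 genes, of which 144 were higher and 61 lower in KO (limma, Benjamini-Hochberg adjusted p under 0.05). By the ratio of mean FPKM, 102 of the higher genes had at least 2 times the WT level and 43 of the lower genes were lower by the same factor or more. Of the 144 higher genes, 15 belonged to the interferon response list and 7 to the T cell activation and effector list. The 2 KO libraries lay on 1 side of the 2 WT libraries at 50.9% of all tested genes, which chance gives for 33.3% where no shift is common to the genes. The values were not centred, and the median FPKM of tested genes was 6.81 and 7.18 in WT and 6.20 and 6.79 in KO. Because a shift between libraries raises this share, the excess does not measure how many genes changed. The median log2 fold change of all tested genes was -0.10. Centring each library on its median moved this to -0.0083 and gave 204 higher and 50 lower genes, so that 80.3% of the calls were higher in place of 70.2%. At all 205 called genes the KO libraries lay on 1 side of the WT libraries, so leaving out any 1 library could not change their direction. Fewer genes passed the threshold in each of those fits. Such a fit leaves 1 library in a genotype and has fewer residual degrees of freedom, so calls were likely to be lost whichever library was left out. With no filter on low genes 0 genes passed the limma threshold, although 2060 of 15457 had an unadjusted p under 0.05 (1706 of 9272 with the filter).

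**Figure D1:**
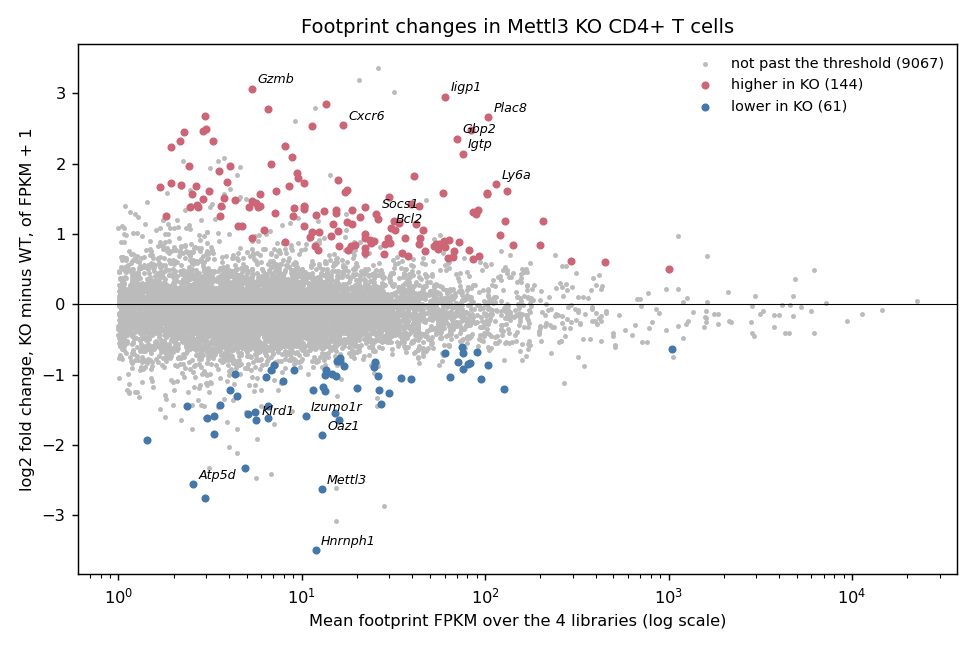
Log2 fold change of FPKM + 1 (KO minus WT, vertical axis) against the mean footprint FPKM over the 4 libraries (horizontal log axis), 1 point per tested gene. The 144 genes past adjusted p 0.05 that were higher in KO are red, the 61 lower genes blue and the remaining 9067 grey, among them some with changes as large but a wider spread between libraries. Mettl3 lies at -2.62 and Iigp1 at 2.95.

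The 12 highest fold changes were taken among called genes with a mean of at least 5 FPKM. Among these 12, Gzmb, the serine protease granzyme B of cytotoxic granules (chromosome 14, 56258838 to 56262260, 3.96 Mb from Mettl3), rose from 0.321 ± 0.109 to 10.4 ± 3.82 FPKM (log2 fold change 3.07, SE 0.27, limma adjusted p = 0.00446). Iigp1, an interferon-inducible GTPase that acts on the vacuoles of intracellular pathogens (chromosome 18, 60376027 to 60392634), rose from 13.0 ± 0.986 to 108 ± 22.8 FPKM (2.95, SE 0.17, limma adjusted p = 0.002). Its call held in each of the 4 fits that left out 1 library, which held for 1 of the 44 named calls, and 25 of the 44 held in none of these fits. Next came Gm4951, a GTPase gene of the same class (2.51 to 24.7 FPKM), the transcription factor gene Bhlhe40 (0.912 to 12.2 FPKM), Plac8 (26.3 to 181 FPKM) and Cxcr6, the receptor for the chemokine Cxcl16 (4.16 to 29.3 FPKM). Tstd1 rose from 2.64 to 20.2 FPKM, Gm4070 from 24.9 to 143 FPKM, and Gadd45g, a growth-arrest and stress gene, from 2.20 to 13.9 FPKM. Gbp2, Igtp and Ifng completed the set. Gm4951 and Gm4070 have closely related copies among which reads could be split, and Tstd1 shares exon sequence with Usf1, so these values are uncertain.

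Among the lower genes taken by the same rule, Hnrnph1, a splicing factor gene, had the lowest fold change (-3.49, SE 0.58, limma adjusted p = 0.033). However, its value in KO library 2, 0.00247 FPKM, was far below the value of 1 read, against 3.12 FPKM in KO library 1 and 18.1 and 26.4 FPKM in WT. Oaz1, the antizyme that restrains polyamine synthesis and is made through a ribosomal frameshift, fell from 20.7 ± 0.35 to 5.13 ± 1.91 FPKM. Klrd1, which encodes the lectin-like receptor CD94, fell from 9.04 to 2.22 FPKM, the small GTPase gene Rhob from 10.4 to 2.73 FPKM, and Izumo1r, which encodes folate receptor 4, from 16.3 to 4.75 FPKM. The deubiquitinase gene Stambpl1 fell from 8.21 to 2.02 FPKM, Ramp1, a partner of the calcitonin receptor-like receptor, from 23.1 to 7.33 FPKM, the alcohol dehydrogenase gene Adh1 from 8.80 to 2.34 FPKM, the epoxide hydrolase gene Ephx1 from 10.0 to 3.02 FPKM and Erh from 40.0 to 14.3 FPKM. The exons of Erh overlap those of Slc39a9. Dynlt1c, a dynein light chain gene, was lower in KO (24.8 to 7.08 FPKM) while its near-identical copy Dynlt1f, chosen after its values were seen, was higher (0.00169 to 4.53 FPKM), so reads may have been split differently between the copies.

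**Figure D2:**
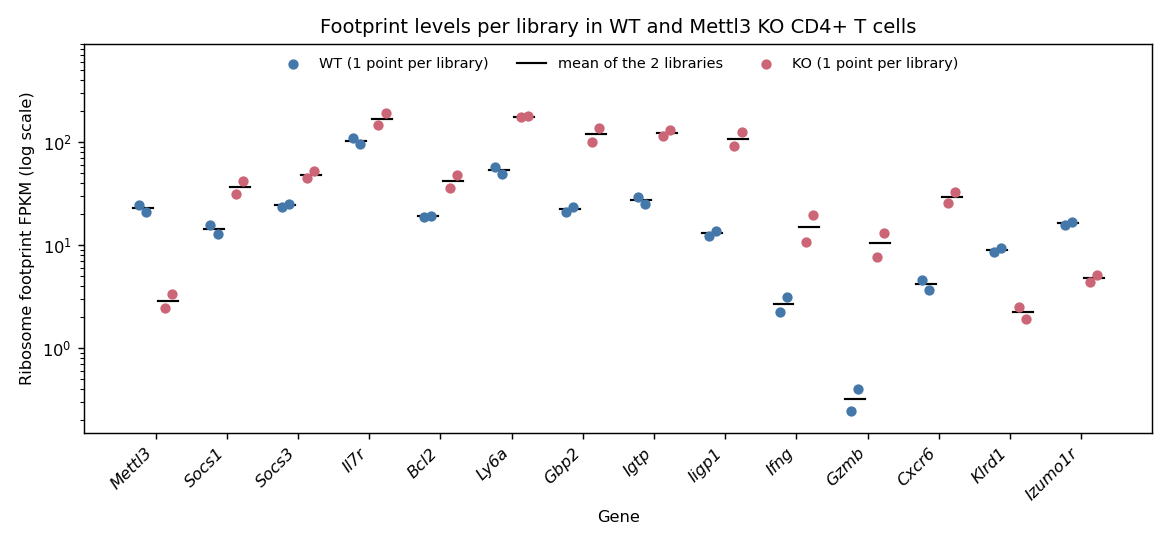
Footprint FPKM (vertical log axis) of 14 genes in each library, with 2 WT points (blue) and 2 KO points (red) per gene and a black bar at the mean of each pair. The KO points of Mettl3, Klrd1 and Izumo1r lie below both WT points. Those of the other 11 genes lie above them, with Il7r at an adjusted p of 0.0759.

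Gene lists fixed beforehand were then compared with all other genes. The interferon response list moved most: 15 of its 33 tested members rose and 0 fell, its median log2 fold change was 0.78, and 25 members were higher when adjusted over the list alone (camera adjusted p = 8.78e-25). Besides Iigp1, the GTPase genes Gbp2 (22.2 ± 1.86 to 119 ± 26.9 FPKM) and Igtp (27.2 ± 2.90 to 123 ± 10.2 FPKM) and Ly6a, which encodes the surface protein Sca-1 (53.4 ± 5.60 to 177 ± 2.29 FPKM), led it. Exons of Igtp overlap those of Irgm2. The list lost its call with an estimated correlation between genes (adjusted p = 0.488 with an estimated correlation), as did every other list called with the preset correlation (adjusted p = 0.674 with an estimated correlation for each of the other 9). With an estimated correlation, camera rests on the 2 residual degrees of freedom, so calls were likely to be lost whatever the correlation. The estimate for the interferon list was 0.062. Over the 10 called lists the estimates ran from 0.025 (cholesterol and fatty acid synthesis) to 0.496 (T cell activation and effector). All were above the preset of 0.01, so the p-values with the preset may be too small. The losses therefore neither show nor exclude that correlation between genes undoes the calls. fry, which asks whether the genes of a list move 1 way on balance without comparing them with other genes, called 0 of the 25 lists, with a lowest adjusted p of 0.0836 for the interferon list.

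The T cell activation and effector list was also higher in KO, with 7 of 19 tested members higher and 0 lower (median 0.64, camera adjusted p = 4.94e-11, 0.674 with an estimated correlation). Adjusted over the list alone, 9 were higher and 1 lower. Gzmb and Bhlhe40 were joined by Ifng, the main cytokine of type 1 helper cells (2.66 ± 0.628 to 15.1 ± 6.20 FPKM), and by the chemokine receptor gene Cxcr3 (3.61 ± 0.929 to 15.4 ± 6.29 FPKM). The other 3 members that rose, named after their values were seen, were Ccl5 (1.76 to 6.89 FPKM), Tbx21, which encodes the type 1 regulator T-bet (0.66 to 2.99 FPKM), and Icos (7.12 to 15.7 FPKM). The list of naive T cell and quiescence genes was not called (median -0.18, camera adjusted p = 0.384). Its 1 called member of 21, Dapl1, fell from 99.1 to 52.5 FPKM, while Ets1 had 299.7 FPKM in WT and 237 FPKM in KO. Adjusted over the list alone, 1 member was higher and 3 were lower. Of 8 tested regulatory T cell genes, Nrp1 rose (0.739 to 4.58 FPKM) and Izumo1r fell. The list had a median of 0.22 and a camera adjusted p of 0.162, with 3 members higher and 1 lower adjusted over the list alone, and it was called higher with no filter on low genes (0.0442).

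Interleukin 7, acting through STAT5, maintains naive T cells, and published work on Mettl3 in T cells concerns this pathway and the SOCS proteins that restrain it. Socs1 (chromosome 16, 10782240 to 10785536) rose from 14.3 ± 2.06 to 36.6 ± 7.08 FPKM (log2 fold change 1.29, SE 0.18, limma adjusted p = 0.0172), and Socs3 (chromosome 11, 117966079 to 117970047) rose from 24.5 ± 1.10 to 48.3 ± 5.22 FPKM (0.95, SE 0.14, limma adjusted p = 0.0187). At both genes the KO libraries lay above the WT libraries, so leaving out any 1 library could not change the direction. Their calls were lost in those fits, which have fewer residual degrees of freedom. Socs2 (0.446 ± 0.504 and 1.69 ± 0.991 FPKM), Socs4 (18.3 and 16.7 FPKM), Socs5 (1.29 and 0.967 FPKM), Socs6 (3.13 and 3.25 FPKM) and Socs7 (2.89 and 2.88 FPKM) were not past the threshold, each given for WT and then KO. Cish was below the filter, at 0.185 and 0.201 FPKM in WT and 0.707 and 1.13 FPKM in KO. The SOCS list had 2 of 7 tested members higher, over all genes and adjusted over the list alone (median 0.046, mean 0.41, camera adjusted p = 0.0256, 0.674 with an estimated correlation), and its call ended without WT library 2 (0.247).

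The list of IL-7 receptor, JAK and STAT5 genes was called higher (camera adjusted p = 0.00494, 0.674 with an estimated correlation) through 4 of its 14 members, while its median was 0.0037. Adjusted over the list alone, 5 were higher and 1 lower. Among them were Il2rb, a receptor chain for interleukins 2 and 15 (3.48 to 13.6 FPKM), Il4ra, the interleukin 4 receptor chain (43.6 to 83.1 FPKM) and the kinase gene Pim1 (40.9 to 77.6 FPKM). Il7r itself had 103 ± 9.32 FPKM in WT and 169 ± 32.5 FPKM in KO (log2 fold change 0.71, 95% interval 0.34 to 1.07, limma adjusted p = 0.0759), and passed the threshold only when libraries were centred on their medians (0.0441, within a range of 0.0441 to 0.341 over its alternatives). Stat5a (15.8 and 15.7 FPKM) and Stat5b (22.4 and 22.3 FPKM) had log2 fold changes of -0.01 each. In the BCL2 and apoptosis list (median 0.32, camera adjusted p = 2.72e-05, 0.674 with an estimated correlation), the survival gene Bcl2 rose from 19.0 ± 0.307 to 42.0 ± 9.17 FPKM, the 1 call among 19 members, and 3 were higher adjusted over the list alone. Mcl1 had 139 FPKM in WT and 189 FPKM in KO, and Casp8 had 35.2 and 33.6 FPKM.

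The replication-dependent histone list was higher in KO (median 0.11, mean 0.26, camera adjusted p = 6.02e-05, 0.674 with an estimated correlation), with 4 of 35 members higher, and 10 adjusted over the list alone. Hist1h2be rose from 29.6 to 58.1 FPKM, Hist1h3c from 50.0 to 93.6 FPKM, Hist1h3d from 49.9 to 84.8 FPKM and Hist1h3e from 60.2 to 103 FPKM, though copies of these genes are close to identical and reads may be shared. The proliferation list was called higher (median 0.079, camera adjusted p = 0.0121, 0.674 with an estimated correlation) with 0 of 22 members past the threshold and 2 higher adjusted over the list alone. Its call ended without WT library 1 (0.163), and its direction turned to down among genes of at least 5 FPKM (0.885). Tubb5 had 72.7 FPKM in WT and 76.1 FPKM in KO, and Pcna had 52.2 and 39.0 FPKM.

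Among genes of the translation machinery, 1 initiation factor gene passed the threshold. The cytosolic ribosomal protein list was called lower than other genes (median -0.25 against -0.10 for all genes, camera adjusted p = 0.00405, 0.674 with an estimated correlation) with 0 of 78 members past the threshold. Adjusted over the list alone, 22 were lower and 1 higher, and without KO library 2 the call ended (0.446). The most abundant members, Rplp1 (22298 and 23137 FPKM) and Rps29 (14962 and 14242 FPKM), had log2 fold changes of 0.052 and -0.072. Of 47 initiation and elongation factors, Eif1ax was lower (90.8 to 59.4 FPKM, limma adjusted p = 0.0499, range 0.0379 to 0.306 over its alternatives), with 0 calls adjusted over the list alone and a camera adjusted p of 0.542. Eef1a1 had 3285 and 2989 FPKM, and Eef2 had 877 and 838 FPKM. The aminoacyl-tRNA synthetases (0 of 20 past the threshold, 1 higher adjusted over the list alone, camera adjusted p = 0.439) included Dars at 71.5 and 56.9 FPKM and Sars at 45.5 and 41.1 FPKM.

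**Figure D3:**
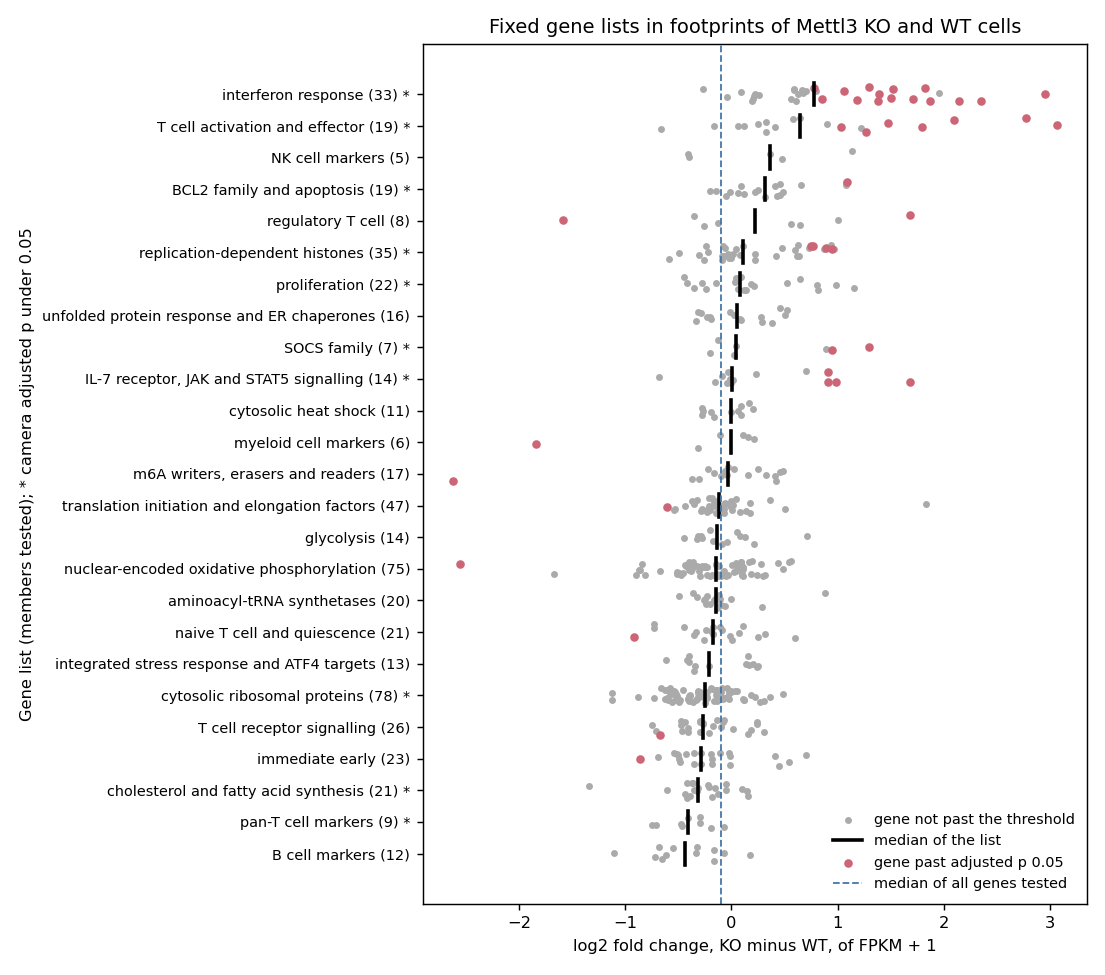
Log2 fold change of FPKM + 1 (KO minus WT, horizontal axis) of each tested member of the 25 fixed gene lists with at least 5 tested members (vertical axis, members tested in brackets). Red points are genes past adjusted p 0.05, black bars list medians, the dashed line the median of all genes (-0.10), and an asterisk a camera adjusted p under 0.05 with the preset correlation. The interferon list has the highest median, 0.78, and the B cell markers the lowest, -0.44.

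Among metabolic and stress lists, the cholesterol and fatty acid synthesis list was called lower (median -0.31, camera adjusted p = 0.0407, 0.674 with an estimated correlation) with 0 of 21 members past the threshold on either adjustment. Its call ended without WT library 1 (0.111), WT library 2 (0.0622) or KO library 1 (0.13), with a pseudocount of 5 (0.0516) and among genes of at least 5 FPKM (0.0592). Acly had 24.1 and 20.6 FPKM and Fdps 26.6 and 19.4 FPKM. Glycolysis (0 of 14, camera adjusted p = 0.779) included Pkm at 263 and 210.1 FPKM and Pgk1 at 142 and 117 FPKM. In nuclear-encoded oxidative phosphorylation (camera adjusted p = 0.355), 1 of 75 members was lower, over all genes and adjusted over the list alone. This was Atp5d, at 3.42 and 6.81 FPKM in WT and 0.000696 and 0.00145 FPKM in KO, values far below that of 1 read. Atp5k (728 and 819 FPKM) and Atp5l (330.0 and 356 FPKM) were the most abundant. The integrated stress response list (0 of 13, camera adjusted p = 0.74) included Atf4 at 48.7 and 36.8 FPKM and Ppp1r15a at 112 and 84.4 FPKM. The unfolded protein response list (0 of 16, camera adjusted p = 0.162) included Calr at 143 and 196 FPKM and Hspa5 at 152 and 185 FPKM. The cytosolic heat shock list (0 of 11, camera adjusted p = 0.815) included Hspa8 at 1229 and 1275 FPKM and Hsp90ab1 at 443 and 390 FPKM. Its median and mean were negative but above the median of all tested genes (-0.10), and its test against all other genes pointed up. Of 23 immediate early genes (camera adjusted p = 0.335), Klf6 fell from 133 to 72.9 FPKM, with 2 members higher and 6 lower adjusted over the list alone. Junb had 401 and 285 FPKM (limma adjusted p = 0.0595, range 0.0446 to 0.320 over its alternatives) and Tnfaip3 had 185 and 298 FPKM (limma adjusted p = 0.0647, range 0.0413 to 0.326). Both passed the threshold among genes of at least 5 FPKM (0.0446 and 0.0413), and Tnfaip3 also with quantile normalization (0.0486). Of 26 T cell receptor signalling genes (camera adjusted p = 0.0858), 1 was lower over all genes and 2 were lower adjusted over the list alone, and the list was called lower with a pseudocount of 5 (0.0196), with no filter on low genes (0.0222) and with quantile normalization (0.0488). Ptprc had 367 and 335 FPKM and Lck had 184 and 159 FPKM.

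Markers of T cells and of cells that could remain in a T cell isolation were compared in the same way. The pan-T cell markers were called lower (median -0.41, camera adjusted p = 0.0256, 0.674 with an estimated correlation) with 0 of 9 past the threshold and 3 lower adjusted over the list alone, and the call ended without WT library 2 (0.163) or KO library 1 (0.0739). Cd4 had 95.9 ± 1.74 and 91.7 ± 13.7 FPKM and Cd2 had 166 and 145 FPKM. B cell markers stood lower in KO library 1 than elsewhere, with Cd74 at 79.3 and 49.6 FPKM in WT and 30.8 and 79.9 FPKM in KO, and H2-Ab1 at 66.0 and 47.6 FPKM in WT and 22.5 and 58.3 FPKM in KO. Of the 12 tested, 0 were past the threshold on either adjustment (median -0.44, camera adjusted p = 0.355), but the list was called lower without KO library 2 (8.29e-05) and without WT library 2 (0.0175). Of 6 myeloid markers (camera adjusted p = 0.55), Tyrobp, a signalling adaptor of myeloid and natural killer (NK) cells, fell from 5.77 to 0.855 FPKM, over all genes and adjusted over the list alone. Cst3 had 26.8 and 24.8 FPKM and Lyz2 had 16.4 and 13.2 FPKM. Of 5 NK cell markers 0 passed on either adjustment (median 0.36, camera adjusted p = 0.236), with Eomes at 2.61 and 4.003 FPKM and Prf1 at 2.697 and 3.74 FPKM. Cd8b1, the 1 tested marker of CD8 T cells, had 1.27 and 0.919 FPKM. Erythroid, platelet, thymocyte and stromal markers had too few tested genes for a list test. Hba-a1 varied between libraries (3.50 and 18.1 FPKM in WT, 8.07 and 39.8 FPKM in KO), as did Hbb-bs (2.66 and 2.93 FPKM on average). Itgb3 had 16.4 and 15.9 FPKM, Dntt had 3.73 and 1.75 FPKM, Cd1d1 had 12.5 and 12.03 FPKM, Pecam1 had 30.4 and 31.1 FPKM, and Vim had 37.7 and 28.1 FPKM. Mitochondrially encoded genes were not analysed here.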

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

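Protein-coding genes only, genes without exon overlap, genes without a genotype below 1 read, and array weights were settings chosen after the data were seen; the other settings were planned, and the planned comparison with the authors' own test was not run, nor were the tests that need input RNA. Against 144 higher and 61 lower genes by limma, 0 and 0 were called with no filter on low genes (2060 of 15457 at an unadjusted p under 0.05), where Mettl3, which has no value without overlapping genes, had a log2 fold change of -2.623 and an adjusted p of 0.166. Keeping small RNA genes gave 56 and 27, dropping the variance trend 46 and 21, and a mean of at least 5 FPKM 152 and 101. The cause was not tested. Without 1 library the counts ranged from 3 (without KO library 2) to 36 (without WT library 1) higher and from 1 to 21 lower, and Mettl3 from -2.788 (without KO library 2, adjusted p 0.0512) to -2.458. These fits assume that the lone library varies like the other genotype. They have fewer residual degrees of freedom, so fewer calls were likely whichever library was left out. With replicate number as a block, 120 genes were higher and 49 lower, of which 111 and 43 were shared, and 9 of the 10 lists were called, without cholesterol and fatty acid synthesis (adjusted p 0.053), while Hba-a1 was called higher (limma adjusted p 0.0298, range 0.0298 to 0.997 over its alternatives). Deviations of same-numbered libraries had a correlation of -0.091, the labels do not say whether the numbers pair the libraries, and the file headers number the WT libraries differently from the titles. The block used the titles' numbers. No pairing was assumed, though depth was similar within a number. Of the 10 lists called, 0 were called with an estimated correlation and 0 by fry. The lower depth of replicate 2, 3400000 and 2810000 reads by the estimate, limits low genes most.

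With a reversed direction and no call, lists had these adjusted p: cytosolic heat shock 0.8851 with no filter and 0.9985 with quantile normalization, NK cell markers 0.9552 with no filter, proliferation 0.885 at a mean of at least 5 FPKM (called higher in the full data), glycolysis 0.986 in protein-coding genes and 0.6182 without overlapping genes, and the integrated stress response 0.7435 without overlapping genes. The cause was not tested. Genes near 0 turned positive when libraries were centred: Stat5b 0.08792, Stat5a 0.0851, Casp8 0.03895, Rps29 0.02253, Cd4 0.02381, Itgb3 0.04733, Cd1d1 0.03706 and Eef2 0.02839. Quantile normalization gave Stat5b 0.05083, Stat5a 0.07537, Casp8 0.003102, Itgb3 0.04052, Cd1d1 0.03092, Eef2 0.0772 and Eef1a1 0.06774. Both scalings remove the median shift of -0.10, which exceeds most of these fold changes.

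Without 1 library, log2 fold changes crossed 0 for Socs6 (-0.2005 to 0.2917), Socs7 (-0.2577 to 0.2994), Socs5 (-0.4246 to 0.02354), Mettl14 (-0.1832 to 0.2222), Stat5b (-0.07476 to 0.0615), Stat5a (-0.1022 to 0.0833), Cd74 (-1.002 to 0.3447), H2-Ab1 (-1.281 to 0.05463), Casp8 (-0.2196 to 0.1083), Cd8b1 (-0.6343 to 0.2777), Hspa8 (-0.25 to 0.4285), Rplp1 (-0.01978 to 0.123), Rps29 (-0.1481 to 0.004023), Hba-a1 (-0.03218 to 2.138), Hbb-bs (-0.5406 to 0.6257), Hnrnpc (-0.2064 to 0.005652), Atp5l (-0.08365 to 0.2893), Cd4 (-0.2218 to 0.08031), Itgb3 (-0.1411 to 0.0467), Tubb5 (-0.04307 to 0.1788), Pecam1 (-0.04228 to 0.1159) and Cd1d1 (-0.1578 to 0.0428). None of these was called in the full data. Lists that changed direction had adjusted p of 0.1078 to 0.9538 (naive T cell), 0.05653 to 0.6901 (oxidative phosphorylation), 0.4458 to 0.9077 (integrated stress response), 0.09405 to 0.2745 (heat shock), 0.6732 to 0.8991 (glycolysis) and 8.288e-05 to 0.5325 (B cell markers, lowest without KO library 2).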

Other observations

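The gene families below, and the tests of NK cells, of a genome segment as the place of the effector genes, of an effector share and of failed estimates, were chosen after the values were seen. Beyond the fixed lists, which hold some members of these families, the guanylate-binding proteins, interferon-inducible GTPases that act on intracellular pathogens, were higher in KO in 9 of 9 tested members (median log2 fold change 1.35), and the immunity-related GTPases in 9 of 10 (1.55), by limma adjusted p. Both medians, and those of the families that follow, kept their sign when libraries were centred or quantile normalized. Among the immunity-related GTPases, Tgtp1 rose from 51.0 to 153.6 FPKM. Of 11 class I MHC heavy chains, 3 were higher, among them H2-K1 (834 to 1180 FPKM), and of 12 genes that load class I molecules with peptide, the transporter genes Tap1 and Tap2 were. Of 9 class II genes, H2-DMa rose from 6.52 to 24.95 FPKM while the family's median was -0.33. Of 11 chemokine receptors, Ccr2, Cxcr3 and Cxcr6 were higher and Cxcr4 fell from 53.7 to 25.3 FPKM. Of 8 GIMAP genes, GTPases of lymphocytes, 3 were higher (median 0.25), and so were 4 of 21 NF-kB pathway genes (median 0.25), among them Nfkb2 (13.0 to 23.9 FPKM). Of the histone clusters, 6 of 9 Hist1h3 genes, 4 of 15 Hist1h2b genes and 1 of 11 Hist1h4 genes were higher, with medians of 0.77, 0.85 and -0.11, though near-identical copies share reads.

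Small RNA genes, left out of the tests above, were examined when they were kept. Of 129 that passed the filter, 0 were higher and 6 lower in KO by limma, with 21 at an unadjusted p under 0.05. Of the lower ones Mir1927, Mir425, Mir3535, Mir29c and Mir1291 are listed at 0 in both KO libraries. The reads behind their WT values are unknown, and for Mir425 and Mir3535 the ratio of WT library 1 to WT library 2 was 0.612, that of equal read counts in both, so the calls of these 5 genes set an unknown number of reads against a listed 0. Snora75 had 1066 and 1404 FPKM in WT and 493 and 410 FPKM in KO.

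Of the interferon and effector lists, 15 of 33 and 7 of 19 tested members were higher in KO by limma. Both list calls were lost when camera estimated the correlation, on 2 residual degrees of freedom (camera adjusted p = 0.488 and 0.674 with an estimated correlation). A genome segment around Mettl3 that differs between the mice is argued against as the place of the interferon genes. Of the 15 called, 0 lay within 20 Mb of Mettl3, and they lay on 11 chromosomes. Of the 7 called effector genes, 1, Gzmb, lay within 20 Mb, at 3.96 Mb, so the segment stays open as the place of Gzmb. It is not the place of Ifng (chromosome 10), Bhlhe40 (chromosome 6) or Cxcr3 (chromosome X). Gene positions are set by which genes the lists hold. They cannot decide whether such a segment acts on genes elsewhere. NK cells left in the KO cells cannot be told apart from a change within T cells, since the markers moved in both directions. The NK list fixed beforehand had a median log2 fold change of 0.36 and a camera adjusted p of 0.236. Of its 5 tested members, Gzma, Prf1 and Eomes were positive, and 0 passed the threshold. The receptor and adaptor genes Klrd1, Klrk1, Klre1, Klrc1 and Tyrobp, picked as a set after their values were seen, were all negative, with a median of -0.432. Klrd1 (9.04 to 2.22 FPKM) and Tyrobp (5.77 to 0.855 FPKM) were called lower (limma adjusted p = 0.0102 and 0.0172). A larger share of effector or memory cells among the KO cells cannot be told apart from a change within naive cells either, since neither the naive list (camera adjusted p 0.384) nor Cd44 (log2 fold change 0.116) decides. An effect of Mettl3 loss itself, on mRNA or on translation, stays open, since input RNA was not analysed here.

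Of the tested genes, 85 had a value above 0 but below that of 0.5 reads, at the length of their longest annotated transcript, in at least 1 library (25, 28, 25 and 41 in WT 1, WT 2, KO 1 and KO 2). Failed estimates that hit libraries regardless of genotype are a candidate explanation: of 20 genes with 2 such libraries, 7 had both in 1 genotype, against 33.3% by chance (one-sided exact binomial p = 0.521). Reads shared with an overlapping gene are argued against as the explanation of most of these genes. Of the 85, 27.1% overlapped another gene's exon, against 23.2% of the others (two-sided Fisher exact p = 0.438). This test cannot exclude that overlap explains some of them, and near-identical copies elsewhere in the genome were not tested. No biological explanation was tested. Of the 205 calls, 9 had such a value and 6 had it in both libraries of a genotype, namely 0610037L13Rik, Atp5d and Spns1 in KO and Cntf, Dynlt1f and Rabggtb in WT.

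The 4 libraries can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The split by genotype gave 205 calls, as 1 of the 3, and the highest of the other splits gave 2. Each other split puts 1 WT and 1 KO library in each group. A genotype difference then widens the spread within groups and lowers the calls, so these counts do not give the number expected by chance.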
